A study of Sus scrofa with 24 samples.

How the data were processed

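RNA of peripheral blood mononuclear cells (PBMNCs), isolated by density gradient from the blood of pigs, was measured on 24 Affymetrix porcine arrays, with 1 biotin-labelled sample for each array. Each of the 6 groups held 4 animals, 2 females and 2 males, fed for 4 months. The groups were standard chow (CT), chow with grape extract and resveratrol (CT-GE-RES), an atherogenic diet (AD), and the same diet with grape extract (AD-GE), with both supplements (AD-GE-RES) or with resveratrol (AD-RES). Per the submitters' processing notes the tools were RMA and GCOS; their versions and roles were not given in the sources used here. The deposited values were 1 intensity per probe set and array on a linear scale, and array medians lay between 38.6 and 41.2. The number of arrays limits the precision of every value.

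All values were taken to log2. Of 24123 probe sets, 124 Affymetrix control probe sets were set aside, and of the other 23999 the lowest 25% by mean over all arrays (mean log2 intensity under 3.57) were left out, which left 17999. Gene names came from the platform's annotation: 8540 of the tested probe sets had 1 symbol, 168 several and 9291 none, and the 1-symbol sets covered 6033 genes. Positions on a genome were not used here.

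A linear model with the 6 group means and sex was fitted to all 24 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (17 residual and 3.60 prior degrees of freedom). All tests were two-sided, and p-values were adjusted by Benjamini and Hochberg over the probe sets tested, with a threshold of 0.05. The p-values measure spread between animals. The 5 comparisons of the study were AD against CT, each supplemented atherogenic group against AD, and CT-GE-RES against CT. The difference between the supplement's effect on the 2 diets was also tested. A moderated F test compared the supplemented atherogenic groups with each other, without AD. Further tests were the atherogenic diet averaged over groups without and with both supplements, the sexes, and the interaction of sex with AD against CT. The interaction came from a fit of all 24 arrays with 12 diet and sex groups. Results for females or males alone were contrasts of 2 against 2 animals in that fit, so their spread came from all 12 groups. Single values of 4 against 4 animals were compared by exact permutation, which can give no p under 0.0286.

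The comparisons, filter, gene lists, named gene rule and most alternatives were fixed before the data were examined. In each comparison and direction the rule named 12 genes: those called with the largest fold change, with free places going to the smallest p. It added up to 4 members with the smallest p from each called list, and a panel of 15 genes of lipid metabolism and inflammation. The rule did not fix the probe set of a panel gene; the one with the highest mean was taken with values in view. The genes named for sex and for the interaction of sex and diet were chosen after their values were seen.

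Of 32 gene lists written from textbook knowledge, for cell types, lipid metabolism, inflammation, stress and cell machinery, 28 had at least 5 measured genes (7 to 64) and were tested. Each gene was represented by its probe set with the highest mean. Lists were tested against all other genes with limma's camera at a preset correlation of 0.01; camera with a correlation estimated from the arrays and limma's fry were run beside it. The p for members of a list was also adjusted over the list alone.

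The method was tested on simulated data for the comparison of AD with CT. With 50 probe sets for each size of change, limma called 34% of true 1.41-fold changes, 90% of 2-fold changes and 100% of 4-fold changes, with 10 false calls among 172. A list shifted by 0.5 was found at a camera adjusted p of 1.93e-20, with 0 of 27 other lists called. The simulated list result and count of false calls may not hold for genes that vary together. When the residuals of the arrays were dealt at random, in 100 draws for AD against CT, camera at the preset correlation called a median of 6 lists (0 to 12) and at least 1 list in 99 draws. With an estimated correlation it called any list in 2 draws.

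The 3'/5' ratio of an array was the mean log2 ratio of the 3' to the 5' probe set over 3 control transcripts (GAPDH, actin and EF1A). A ratio of the same kind was taken as the mean over 12 pairs of probe sets for the spiked transcripts, a choice made before its values were seen. Relations across arrays were tested with 100000 permutations, and those of the list means with the ratio with 10000 for each list. Alternatives were: no sex term, only the arrays of the groups compared, no filter or the lower 50% left out, repeated quantile normalization and median centring. Others were array weights, another variance prior, and list means of monocyte, B cell and erythroid genes as covariates. Also run were contrasts within each sex, each array left out in turn, and the mean of all probe sets of a gene. A further one was an unadjusted p under 0.01 with a fold change of at least 1.5. Added after seeing the data were the 3'/5' ratio as a covariate, omission of the 2 arrays with the lowest array weights (CT 4 and AD-GE-RES 1), all 4 atherogenic groups against both control groups, and the interaction of sex with all 6 diets. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.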

Results

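Expression in peripheral blood mononuclear cells was measured in 24 pigs, 4 for each of 6 diets, with 2 females and 2 males in each group. The standard chow group (CT) and its supplemented counterpart (CT-GE-RES) were set beside 4 groups on an atherogenic diet rich in beef tallow (5.5%) and coconut oil (10%), with cholic acid at 1%: AD, AD-GE, AD-GE-RES and AD-RES. Grape extract (GE) was given at 1 g and resveratrol (RES), a stilbene found in grape skin, at 18 mg per 70 kg of body weight. Values are log2 intensities with SD or SE, and differences are log2. Across arrays the leading principal component, with 20.5% of the variance, followed the 3'/5' ratio of the control transcripts (Pearson r 0.942, Spearman rho 0.890, each over 24 arrays with a permutation p of 1e-05, the smallest possible, and r 0.931 without the 2 farthest arrays). Within the diet groups r was 0.943 and rho 0.94. The ratio ran from 1.37 to 4.39 over the arrays, with group means of 3.15 ± 1.13 (SD, n = 4) in CT, 2.19 ± 0.87 in AD, 2.46 ± 0.82 in AD-GE, 2.69 ± 1.24 in AD-GE-RES, 1.92 ± 0.23 in AD-RES and 2.20 ± 0.89 in CT-GE-RES. Over the 28 lists it was related to 4: T cell genes (rho −0.883, r −0.908, without the 2 farthest −0.879), MHC class II genes (rho −0.861, r −0.831, without them −0.781) and apoptosis genes (rho −0.831, r −0.819, without them −0.765), each with an adjusted permutation p of 9.33e-04, and proteasome genes (rho −0.597, r −0.557, without them −0.487, adjusted permutation p 0.0140).

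**Figure D1:**
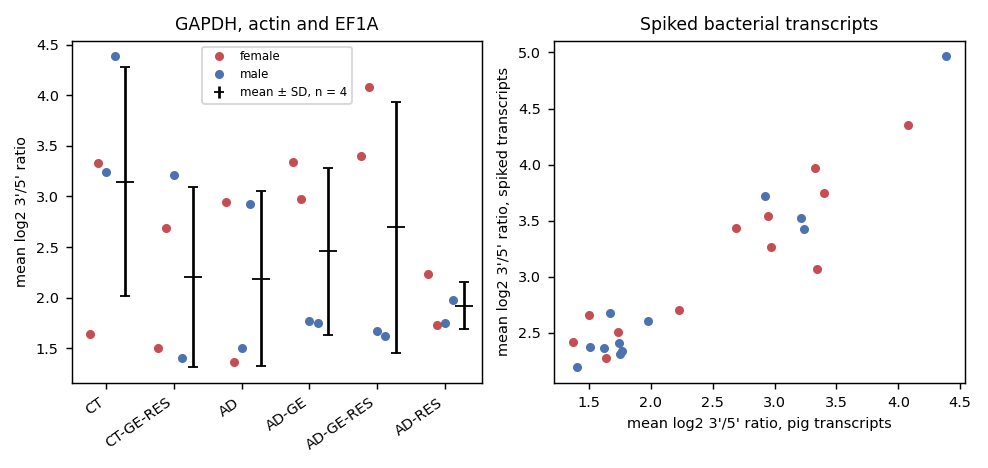
Left, mean log2 3'/5' ratio of 3 control transcripts (y axis) in each diet group (x axis), with points for animals, red female and blue male, and bars for mean ± SD (n = 4). Right, the same ratio against that of the spiked transcripts (both log2), 1 point for each of 24 arrays: the ratio reached 4.39 in a CT male, and the measures had an r of 0.949.

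The comparison of AD with CT addressed how the circulating cells responded to a diet high in fat. FKBP5, a glucocorticoid-induced chaperone of the glucocorticoid receptor, stood at 5.74 ± 0.20 (SD, n = 4) in AD and 4.88 ± 0.24 in CT, a difference of 0.86 (SE 0.18). A second FKBP5 probe set with stronger signal differed by 0.47 (SE 0.23). CXCR4, the receptor of the chemokine CXCL12, was 0.91 (SE 0.21) higher in AD, and S1PR1, through which sphingosine 1-phosphate guides lymphocytes out of lymphoid organs, was 0.69 (SE 0.15) higher. OCRL, a phosphoinositide phosphatase, stood at 5.06 ± 0.04 (SD, n = 4) in AD and 5.55 ± 0.07 in CT, and RUFY1, an endosomal adaptor, and XPA, a factor of nucleotide excision repair, were lower in AD, with differences of −0.52 (SE 0.13) and −0.56 (SE 0.14). The neutrophil-attracting chemokine CXCL8 differed by 2.04 (SE 0.91) and the cholesterol exporter ABCA1 by −0.59 (SE 0.31). None of these genes passed in both sexes together: limma called 0 of 17999 probe sets (smallest adjusted p 0.633), with 1149 at an unadjusted p under 0.05, 585 higher and 564 lower, where independent tests give 899.95 by chance and other splits of the same 8 arrays gave a median of 1202.5. In males alone limma called 242, among them S1PR1 (1.14, limma adjusted p = 0.00995), CXCR4 (1.54, 0.0133), RUFY1 (−0.61, 0.0443) and XPA (−0.78, 0.0443). In females alone it called 1, none of these genes. Of those called in males with a symbol, CAVIN2 (−3.49), DDAH1 (−3.38), VWF (−3.29) and HBE1 (−2.99) differed most. List means in CT and AD males were 0.94 and −0.75 for platelet, 0.79 and −0.27 for erythroid and 0.91 and −0.11 for neutrophil genes, relative to all arrays. Neutrophil genes stood at 1.83 in CT 4, while the other CT animals reached at most 0.03. Platelet genes were highest in CT 3 among the CT animals, and erythroid genes varied widely in CT (SD 0.87). CT 4 also had the highest 3'/5' ratio of all arrays (4.39) and the lowest mean correlation with the other arrays (0.957). Whether the differences in list means account for the calls in males was not tested, nor was how far those calls rest on CT 4. With the 3'/5' ratio in the fit the count in males was 214, with 91 higher and 123 lower against 169 and 73 without it. At an unadjusted p under 0.01 with a fold change of at least 1.5, 63 probe sets passed. For 91.6% of probe sets the 95% interval of the difference lay within 2-fold. The animals of AD and CT did not overlap for 18 of the 24 genes that the rule named. In this and the other comparisons the rule took genes with the smallest p in the same arrays, which favours such separation. Over all 17999 probe sets the animals did not overlap for 493, a share just under the 2.86% that chance gives.

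Of 28 gene lists, camera at the preset correlation called 7 between AD and CT, and none of them with an estimated correlation. Among genes of the glucocorticoid response 13 of 14 were higher in AD, with a median of 0.28, CXCR4 at 0.91 and NFKBIA, the inhibitor of NF-kB, at 0.60 (camera adjusted p = 0.000520, and adjusted p = 0.764 with an estimated correlation). Inflammatory cytokines and NF-kB targets were higher in 20 of 25, with a median of 0.27 (camera adjusted p = 0.00326, and adjusted p = 0.764 with an estimated correlation), including the chemokine CXCL2 at 1.84 (SE 0.66), while the death ligand TNFSF10 stood at −1.19 (SE 0.41). Immediate early genes were higher in 19 of 22, with a median of 0.26 (0.00331 by the same test, and adjusted p = 0.764 with an estimated correlation), with NR4A2, an orphan nuclear receptor, at 1.07 and SOCS3, a brake on cytokine signalling, at 0.39. T cell genes were higher in 13 of 14, with a median of 0.31 (0.00156, and adjusted p = 0.764 with an estimated correlation), among them the interleukin 7 receptor IL7R at 0.58 and the checkpoint receptor CTLA4 at 0.36; the 3'/5' ratio, AD minus CT, was −0.96 (exact permutation p = 0.143). Ribosomal protein genes were higher in 45 of 58, with a median of 0.05 (1.22e-04, and adjusted p = 0.764 with an estimated correlation), RPS9 at 0.43 and RPL6 at 0.23. Lower in AD were platelet genes, 11 of 13 with a median of −0.55 (0.0273, and adjusted p = 0.764 with an estimated correlation), including the caveolar protein CAVIN2 at −1.51 (SE 0.70) and the ADP receptor P2RY12 at −0.67. Without CT 3, whose platelet mean stood above the −0.20 to 0.38 of the other CT animals, the median was −0.03. Cell cycle genes were lower in 20 of 25, with a median of −0.26 (0.0225, and adjusted p = 0.764 with an estimated correlation), such as the centromere protein CENPF at −0.78 and the replicative helicase subunit MCM2 at −0.50. The smallest fry adjusted p was 0.695. The medians in females and in males were 0.02 and 0.60 for the glucocorticoid, 0.07 and 0.50 for the inflammatory, 0.08 and 0.32 for the immediate early, 0.08 and 0.52 for the T cell and 0.02 and 0.09 for the ribosomal list. For platelet genes (0.57 and −1.74) and cell cycle genes (0.21 and −0.60) they had opposite signs. The difference between the sexes was not tested for lists. In males the 3'/5' ratio averaged 3.81 in CT and 2.22 in AD, and in females 2.48 and 2.16. With residuals dealt at random in place of AD and CT, camera at the preset correlation called at least 7 lists in 44 of 100 draws. Over all genes 0 members of these lists passed by limma; adjusted over the list alone 1 did, CXCR4 in the glucocorticoid list, and 2 did in the adhesion list, which was not called. With the 3'/5' ratio in the fit 3 of the 7 calls remained (ribosomal 8.68e-05, platelet 0.0267 and inflammatory 0.0267), while the camera adjusted p was 0.0502 for the glucocorticoid, 0.181 for the immediate early, 0.492 for the T cell and 0.492 for the cell cycle list. Without the arrays CT 4 and AD-GE-RES 1 the T cell (0.208) and cell cycle (0.926) calls were lost, and without CT 1 12 lists were called. In females the differences of IL7R (−0.29), CAVIN2 (0.48) and CENPF (0.48) had the opposite sign.

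**Figure D2:**
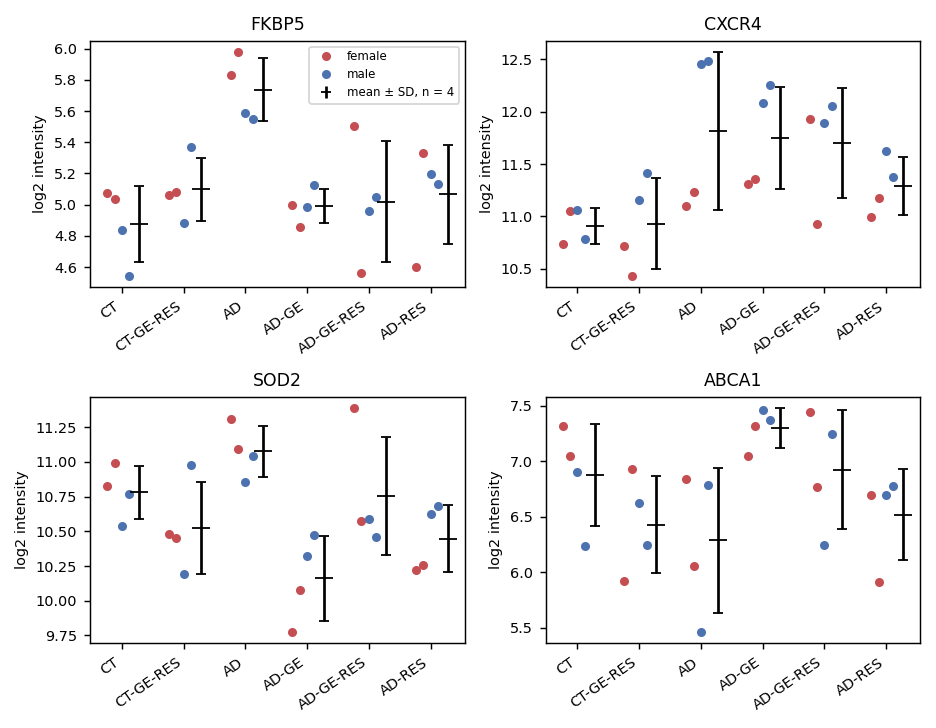
Log2 intensity (y axis) of FKBP5 (the probe set near log2 5), CXCR4, SOD2 and ABCA1 in the 6 diet groups (x axis); points are animals, red female and blue male, and bars are mean ± SD (n = 4). FKBP5 averaged 5.74 in AD and 4.88 in CT, and ABCA1 averaged 6.29 in AD and 7.30 in AD-GE.

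AD-GE against AD addressed what a grape extract did in animals on the atherogenic diet. SOD2, the mitochondrial superoxide dismutase, stood at 10.16 ± 0.31 (SD, n = 4) in AD-GE and 11.08 ± 0.18 in AD, a difference of −0.91 (SE 0.20). CEBPD, a transcription factor of myeloid inflammation, stood at 10.11 ± 0.13 (SD, n = 4) and 10.90 ± 0.17, and ACSL1, which activates long-chain fatty acids, differed by −0.75 (SE 0.18). DNAJA4, a co-chaperone of HSP70 proteins, was higher in AD-GE by 0.75 (SE 0.16), as was the translation factor EIF4H by 0.66. ABCA1 stood at 7.30 ± 0.18 (SD, n = 4) against 6.29 ± 0.65, a difference of 1.01 (SE 0.31). Of the 10 measured panel genes it alone passed when adjusted over the list alone, with a limma adjusted p = 0.0402. Over all 17999 probe sets limma called 0 (smallest adjusted p 0.458), with 1097 at an unadjusted p under 0.05, 503 higher and 594 lower. With array weights 1 was called, and 74 had an unadjusted p under 0.01 with a fold change of at least 1.5. The 95% interval lay within 2-fold for 92.8%. The groups did not overlap for 21 of the 24 named genes and for 849 of all probe sets, a share above the 2.86% that chance gives. Whether that share exceeds chance was not tested, and probe sets are not independent.

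Each of the 5 lists that camera called in AD-GE was lower than in AD. All 20 monocyte genes were lower, with a median of −0.54 (camera adjusted p = 6.97e-09, and adjusted p = 0.465 with an estimated correlation), TLR2, a receptor for bacterial lipoproteins, at −1.11 and CEBPD at −0.79. The mean of the list was 0.30 ± 0.12 (SD, n = 4) in AD and −0.32 ± 0.22 in AD-GE, relative to its mean over all arrays, without overlap. Interferon response genes were lower in 25 of 26, with a median of −0.55 (1.46e-10, and adjusted p = 0.465 with an estimated correlation), including IFIT2, an antiviral protein, at −1.39 (SE 0.41) and the RNA sensor DDX58 at −0.98. NRF2 and antioxidant genes were lower in 17 of 23, with a median of −0.18 (0.0197, and adjusted p = 0.465 with an estimated correlation). SOD2 at −0.91, HMOX1, which degrades haem, at −0.68 (SE 0.30) and PGD, a pentose phosphate enzyme, at −0.57 were among them. Glucocorticoid response genes were lower in 13 of 14, with a median of −0.34 (0.0221, and adjusted p = 0.532 with an estimated correlation), with ANXA1, a lipid-binding anti-inflammatory protein, at −0.61 and the kinase SGK1 at −0.51. Apoptosis genes were lower in 14 of 17, with a median of −0.15 (0.0478, and adjusted p = 0.465 with an estimated correlation), with CASP1, the protease of the inflammasome, at −0.89 and the adaptor FADD at −0.29; the 3'/5' ratio was 0.27 higher in AD-GE (exact permutation p = 0.514). By limma 0 members passed over all genes, while adjusted over the list alone 3 monocyte genes and 1 antioxidant gene, SOD2, did, and 7 genes over all 28 lists; the smallest fry adjusted p was 0.191. With the ratio in the fit the glucocorticoid (camera adjusted p = 0.0652) and apoptosis (0.104) calls were lost and a T cell call (0.0182) was added. The count of lists was 2 without AD 2, 3 without AD-GE 2, 8 without AD 1, 8 without AD-GE 3 and 9 without AD-GE 4.

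**Figure D3:**
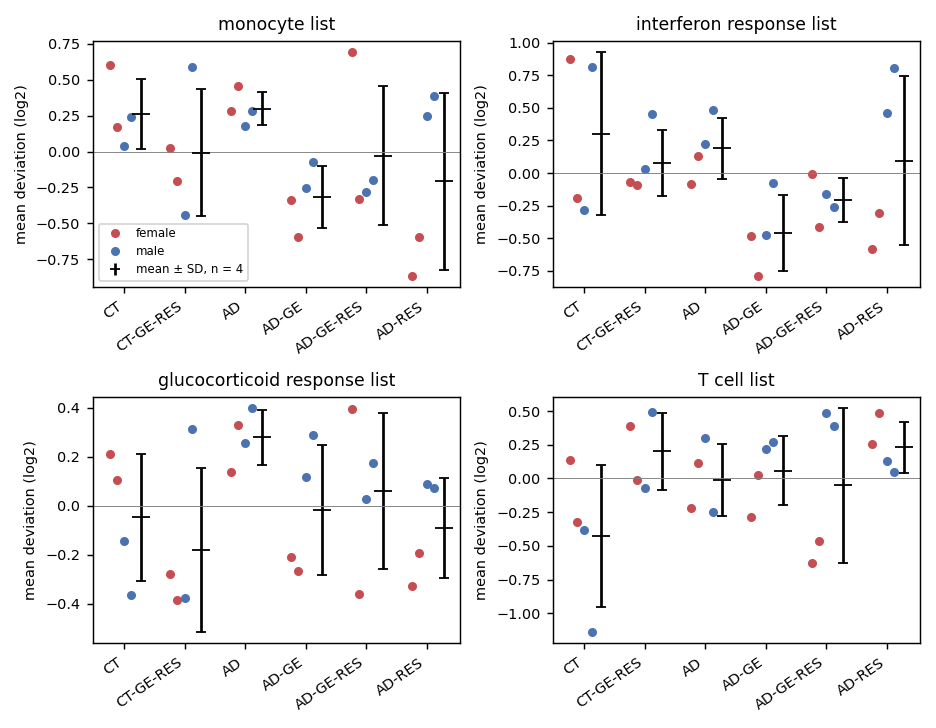
Mean deviation of the genes of 4 lists (monocyte, interferon response, glucocorticoid response and T cell) from their mean over all arrays (y axis, log2) in the 6 diet groups (x axis), with points for animals, red female and blue male, and bars for mean ± SD (n = 4). The monocyte values of the 4 AD animals lay from 0.18 to 0.46 and those of the 4 AD-GE animals from −0.60 to −0.08.

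AD-GE-RES against AD addressed a resveratrol-enriched grape extract on the same diet. FKBP5 stood at 5.02 ± 0.39 (SD, n = 4) in AD-GE-RES and 5.74 ± 0.20 in AD, a difference of −0.72 (SE 0.18), and its second probe set differed by −0.75 (SE 0.23). LFNG, a glycosyltransferase that modifies Notch, differed by −0.49 and GLUL, the glutamine synthetase, by −0.35. UPF3B, a factor of nonsense-mediated decay, was higher by 0.66 (SE 0.21), the kinase MAPK9 by 0.34 and the monoamine oxidase MAOB by 0.36. ABCA1 differed by 0.64 (SE 0.31) and CXCL8 by −0.94 (0.56 in females). By limma 0 of 17999 probe sets passed (smallest adjusted p 1.00), and 432 had an unadjusted p under 0.05, 207 higher and 225 lower, fewer than the 899.95 that chance gives. With an unadjusted p under 0.01 and a fold change of at least 1.5 there were 9. The groups did not overlap for 14 of the 24 named genes and for 227 of all probe sets, a share under the 2.86% that chance gives. The 95% interval lay within 2-fold for 94.7%.

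Camera called 7 lists in AD-GE-RES, all lower than in AD. Interferon response genes were lower in 24 of 26, with a median of −0.35 (camera adjusted p = 1.42e-08, and adjusted p = 0.596 with an estimated correlation), DDX58 at −0.71 and the RNA-activated kinase EIF2AK2 at −0.34. Monocyte genes were lower in 19 of 20, with a median of −0.29 (3.64e-05, and adjusted p = 0.598 with an estimated correlation), CEBPD at −0.37 and the Fc receptor FCGR1A at −0.64. Immediate early genes were lower in 17 of 22, with a median of −0.27 (2.95e-04, and adjusted p = 0.596 with an estimated correlation), SOCS3 at −0.39 and the stress factor ATF3 at −0.59. Glucocorticoid response genes were lower in 12 of 14, with a median of −0.23 (0.00124, and adjusted p = 0.596 with an estimated correlation), and ANXA1 stood at −0.43. Neutrophil genes were lower in 7 of 9, with a median of −0.49 (0.00347, and adjusted p = 0.596 with an estimated correlation), CHI3L1, a chitinase-like lectin, at −1.03 (SE 0.48) and the elastase ELANE at −0.22. Apoptosis genes were lower in 12 of 17, with a median of −0.13 (0.00347, and adjusted p = 0.596 with an estimated correlation), BCL2L1, which protects against cell death, at −0.22 and CASP1 at −0.63. Inflammatory genes were lower in 16 of 25, with a median of −0.08 (0.0417, and adjusted p = 0.645 with an estimated correlation), PTGS2, the inducible cyclooxygenase, at −0.89 and the chemokine AMCF-II at −0.28. The smallest fry adjusted p was 0.840. AD-GE-RES 1 stood apart from its group at 0.69 in monocyte genes, above all AD animals; without it the median was −0.56 for monocyte and −0.41 for inflammatory genes, and without AD-GE-RES 2 it was 0.0033 for inflammatory genes. In females and in males the medians were −0.02 and −0.40 for monocyte genes, and for inflammatory genes they had opposite signs, 0.05 and −0.43. By limma 0 members passed over all genes and 0 adjusted over the list alone. The 3'/5' ratio was 0.51 higher in AD-GE-RES (exact permutation p = 0.486); with it in the fit the camera adjusted p was 0.0661 for apoptosis and 0.112 for inflammatory genes. Without the arrays CT 4 and AD-GE-RES 1 the apoptosis call was lost (0.0757), and without AD-GE-RES 2 4 lists were called.

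AD-RES against AD addressed resveratrol alone on the atherogenic diet. SGK1, a glucocorticoid-induced kinase, differed by −0.75 (SE 0.20) and FKBP5 by −0.67 (SE 0.18). SYS1, a Golgi trafficking protein, differed by −0.56 (SE 0.12) and ARPC4, a subunit of the actin-nucleating Arp complex, by −0.43. XPA was higher by 0.54 (SE 0.14), the motor protein KIF3A by 0.72 (SE 0.22) and the mitochondrial carrier SLC25A21 by 0.46. HMOX1 differed by −0.64 (SE 0.30), ABCA1 by 0.23 (−0.04 without AD 3) and CD14, a co-receptor for endotoxin, by −0.99 (SE 0.77; 0.69 with the 3 cell list means in the fit). By limma 0 of 17999 probe sets passed (smallest adjusted p 0.980), with 801 at an unadjusted p under 0.05, 324 higher and 477 lower, and 42 under 0.01 with a fold change of at least 1.5. In females alone limma called 4 and in males alone 7, and with the 3'/5' ratio in the fit 6 and 22. The groups did not overlap for 16 of the 24 named genes and for 506 of all probe sets, a share just under the 2.86% that chance gives. The 95% interval lay within 2-fold for 93.4%.

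Camera called 6 lists between AD-RES and AD. Monocyte genes were lower in 19 of 20, with a median of −0.48 (camera adjusted p = 2.67e-06, and adjusted p = 0.564 with an estimated correlation), the myeloid transcription factors CEBPB and CEBPD at −0.73 and −0.60. Immediate early genes were lower in 20 of 22, with a median of −0.38 (8.20e-05, and adjusted p = 0.564 with an estimated correlation), SOCS3 at −0.46 and ZFP36, which destabilises cytokine mRNA, at −0.50. Glucocorticoid response genes were lower in 12 of 14, with a median of −0.46 (1.98e-04, and adjusted p = 0.564 with an estimated correlation), SGK1 at −0.75 and the clock gene PER1 at −0.82. Inflammatory genes were lower in 19 of 25, with a median of −0.45 (0.00188, and adjusted p = 0.564 with an estimated correlation), NFKBIA at −0.69 and SOD2 at −0.63. Adhesion and migration genes were lower in 18 of 24, with a median of −0.16 (0.0121, and adjusted p = 0.564 with an estimated correlation), CXCR4 at −0.53 and the integrin ITGB2 at −0.40. Erythroid genes were higher in 9 of 12, with a median of 0.43 (0.0120, and adjusted p = 0.891 with an estimated correlation), the membrane skeleton protein EPB41 at 0.51 and the blood group protein RHCE at 1.27 (SE 0.79). The smallest fry adjusted p was 0.414. By limma 0 members passed over all genes; adjusted over the list alone 3 glucocorticoid genes (SGK1, PER1 and NFKBIA) and 1 monocyte gene (CEBPD) did, and 5 genes over all 28 lists. In females the monocyte median was −1.07 and in males 0.11, the immediate early medians were −0.67 and −0.07, and the erythroid medians were −0.32 and 1.05, with RHCE at −0.80 in females; the difference between the sexes was not tested for these lists. The 3'/5' ratio differed by −0.27 (exact permutation p = 0.543), and with it in the fit all 6 calls remained.

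CT-GE-RES against CT addressed the enriched extract on standard chow. CTLA4, an inhibitory receptor of T cells, stood at 4.58 ± 0.53 (SD, n = 4) in CT-GE-RES and 3.90 ± 0.10 in CT. ABCB1, an efflux pump, was higher by 0.73 (SE 0.21), the deubiquitinase UCHL1 by 1.25 (SE 0.36) and the mitochondrial protein APOO by 0.46. PADI2, which converts arginine to citrulline in proteins, differed by −0.80 (SE 0.22), OCRL by −0.38 (SE 0.10), the gelatinase MMP2 by −0.60 and HMOX1 by −0.64 (SE 0.30). By limma 0 of 17999 probe sets passed (smallest adjusted p 0.700), with 1224 at an unadjusted p under 0.05, 697 higher and 527 lower, and 30 under 0.01 with a fold change of at least 1.5. In males alone limma called 122, 74 higher and 48 lower, and in females alone 0. With the 3'/5' ratio in the fit, which averaged 3.81 in CT males and 2.31 in CT-GE-RES males, the counts were 6 and 1. The CT males of this comparison were also those of AD against CT. The groups did not overlap for 18 of the 24 named genes and for 725 of all probe sets, a share above the 2.86% that chance gives. Whether that share exceeds chance was not tested, and probe sets are not independent. The 95% interval lay within 2-fold for 92.3%.

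Camera called 10 lists between CT-GE-RES and CT, 5 in each direction. All 33 proteasome genes were higher, with a median of 0.23 (camera adjusted p = 6.68e-09, and adjusted p = 0.514 with an estimated correlation), the catalytic subunit PSMB5 at 0.33 (SE 0.10) and PSMA5 at 0.34 (SE 0.11). All 14 T cell genes were higher, with a median of 0.55 (2.09e-05, and adjusted p = 0.514 with an estimated correlation), CTLA4 at 0.68 and CD3G, a chain of the T cell receptor complex, at 0.70. Cytotoxic T and NK cell genes were higher in 7 of 8, with a median of 0.47 (0.0498, and adjusted p = 0.684 with an estimated correlation), the granzyme GZMH at 0.78 and the co-receptor CD8B at 0.64. MHC class I presentation genes were higher in 14 of 16, with a median of 0.21 (0.00353, and adjusted p = 0.514 with an estimated correlation), the class I molecule SLA-6 at 0.40 and the disulfide isomerase PDIA3 at 0.34. Cell cycle genes were higher in 22 of 25, with a median of 0.29 (0.00581, and adjusted p = 0.693 with an estimated correlation); the members with the smallest p were HMGB2, a chromatin protein, at 0.30 and TUBA1B, a microtubule subunit, at 0.29. Erythroid genes were lower in 11 of 12, with a median of −0.56 (5.28e-04, and adjusted p = 0.514 with an estimated correlation), the transcription factor KLF1 at −0.52 and the iron importer SLC25A37 at −0.60. Neutrophil genes were lower in 8 of 9, with a median of −0.71 (0.00176, and adjusted p = 0.514 with an estimated correlation), the antimicrobial peptide gene NPG4 at −1.67 (SE 0.82) and CHI3L1 at −0.95. Monocyte genes were lower in 15 of 20, with a median of −0.23 (0.00115, and adjusted p = 0.693 with an estimated correlation), CEBPB at −0.66 and CEBPD at −0.33. Immediate early genes were lower in 19 of 22, with a median of −0.21 (0.00115, and adjusted p = 0.658 with an estimated correlation), EGR1 at −1.14 and KLF10 at −0.46. Interferon response genes were lower in 19 of 26, with a median of −0.31 (0.00366, and adjusted p = 0.693 with an estimated correlation), the lectin SIGLEC1 at −0.32 while the GTPase GBP1 stood at 0.47. The smallest fry adjusted p was 0.0535 (proteasome and MHC class I), and fry's mixed test, for change in either direction, gave 0.0448 for the proteasome. By limma 0 members passed over all genes, and adjusted over the list alone 1 did, CTLA4. The 3'/5' ratio differed by −0.94 (exact permutation p = 0.143); with it in the fit the T cell median was 0.30 and 9 of the 10 calls remained, without the cytotoxic list (0.193). Without the arrays CT 4 and AD-GE-RES 1 the interferon (0.127), erythroid (0.136), cytotoxic (0.136) and neutrophil (0.186) calls were lost, and without CT-GE-RES 3 5 lists were called. Interferon genes had a median of 0.0036 without CT 1. In females and in males the medians had opposite signs for erythroid (0.23 and −1.09), neutrophil (0.14 and −0.92), cytotoxic (−0.0043 and 0.76) and monocyte genes (−0.48 and 0.0084), and were 0.26 and 0.91 for T cell, 0.69 and 0.03 for cell cycle, 0.12 and 0.32 for proteasome and 0.06 and 0.30 for MHC class I genes. In females GZMH stood at −0.02 and KLF10 at 0.24, and in males CEBPD at 0.03.

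**Figure D4:**
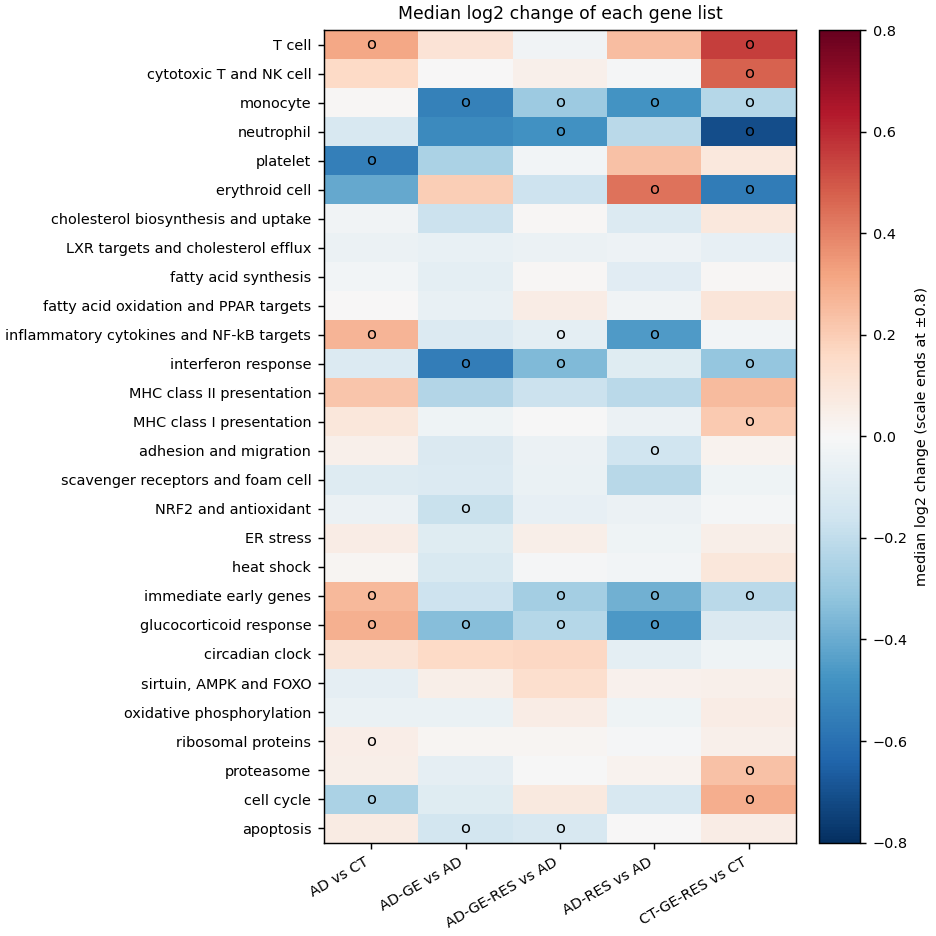
Median log2 difference (colour, from −0.8 to 0.8) of the genes of 28 lists (y axis) in the 5 comparisons (x axis); circles mark a camera adjusted p under 0.05 at the preset correlation. Monocyte genes were lower in each of the 3 supplemented atherogenic groups than in AD (−0.54, −0.29 and −0.48), and 0 lists were called with an estimated correlation.

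Lists of lipid metabolism were called in none of the 5 comparisons. Over these the medians ran from −0.17 to 0.08 for cholesterol biosynthesis and uptake, −0.07 to −0.04 for LXR targets and cholesterol efflux, −0.09 to 0.01 for fatty acid synthesis, −0.06 to 0.10 for fatty acid oxidation and PPAR targets, −0.22 to −0.04 for scavenger receptors, and −0.06 to 0.06 for oxidative phosphorylation. For the sirtuin, AMPK and FOXO list they ran from −0.07 to 0.13, for the circadian clock from −0.08 to 0.17, for heat shock from −0.12 to 0.09, for ER stress from −0.10 to 0.06 and for MHC class II presentation from −0.24 to 0.25. In all, camera called 11 lists in none of the 5 comparisons. The 4 lists with too few measured genes were not tested: in AD against CT all 4 B cell genes were lower (−0.42 to −0.19), all 4 plasma cell genes were higher (0.05 to 0.16), 3 of 4 dendritic cell genes were higher (−0.33 to 0.14) and 2 of 3 aryl hydrocarbon receptor genes were higher (−0.60 to 0.23). Of 140 list results the median, the mean and the camera direction differed in sign in 17, with a median of at most 0.09 in size and 0 of them called. Of the panel of 15, 10 genes were measured. By limma 0 panel genes passed in any comparison over all genes, and 1, 2, 0, 1 and 1 had an unadjusted p under 0.05, in the order of the comparisons above. With the probe set of smallest p for each panel gene the fourth count was 2.

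Whether the enriched extract acted differently on the atherogenic diet and on chow was tested as an interaction. T cell genes were 0.55 higher with the extract on chow, and the difference between the diets had a median of −0.49, lower in 14 of 14 (camera adjusted p = 7.89e-05, and adjusted p = 0.531 with an estimated correlation). For proteasome genes it was −0.26, lower in 32 of 33 (1.20e-07), for MHC class I genes −0.23 in 14 of 16 (0.0189), for MHC class II genes −0.37 in 12 of 14 (0.0197), for apoptosis genes −0.13 in 15 of 17 (0.0101), for cell cycle genes −0.29 in 20 of 25 (0.0259), and for erythroid genes 0.50, higher in 10 of 12 (0.0394). With an estimated correlation the adjusted p = 0.531 for proteasome, MHC class I and apoptosis genes, 0.911 for MHC class II and erythroid genes and 0.961 for cell cycle genes. With the 3'/5' ratio in the fit the camera adjusted p was 0.000591 for proteasome and 1.40e-09 for cell cycle genes, while the calls for T cell (0.566), MHC class I (0.357), MHC class II (0.614), apoptosis (0.413) and erythroid genes (0.490) were lost. For MHC class II genes the direction of the camera test then turned, with a median of −0.02. Among probe sets limma called 0 (smallest adjusted p 1.00, 561 at an unadjusted p under 0.05). Among the 3 supplemented groups, without AD, the moderated F test of limma also called 0 (0.793, 1122). Between pairs of supplemented groups limma called 0 each time, with 1145 at an unadjusted p under 0.05 for AD-GE-RES against AD-GE, 1169 for AD-GE-RES against AD-RES and 989 for AD-GE against AD-RES. The 95% interval of these differences lay within 2-fold for 93.5%, 93.2% and 93.2% of probe sets.

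Averaged over animals without and with both supplements, the atherogenic diet gave 8 list calls by camera. Cell cycle genes were lower in 23 of 25, with a median of −0.38 (camera adjusted p = 1.38e-07, and adjusted p = 0.523 with an estimated correlation), and platelet genes in 11 of 13, with a median of −0.64 (0.00792, and adjusted p = 0.811 with an estimated correlation). Glucocorticoid response genes were higher in 13 of 14, with a median of 0.18 (1.10e-05), immediate early genes in 18 of 22, with 0.24 (7.26e-06), and inflammatory genes in 19 of 25, with 0.26 (8.04e-05), each with an adjusted p = 0.516 with an estimated correlation. Ribosomal protein genes were higher in 48 of 58, with a median of 0.04 (1.67e-05, and adjusted p = 0.738 with an estimated correlation). Proteasome genes were lower in 28 of 33, with −0.07 (0.00792, and adjusted p = 0.811 with an estimated correlation), and interferon genes in 21 of 26, with −0.21 (0.00893, and adjusted p = 0.897 with an estimated correlation). Over all genes limma called 0 (smallest adjusted p 0.247, 1441 at an unadjusted p under 0.05), while adjusted over the list alone 16 genes passed over all 28 lists, of which 5 were in the glucocorticoid, 1 in the inflammatory and 1 in the proteasome list and 9 in lists not called. All 8 list calls remained with the 3'/5' ratio in the fit. All 4 atherogenic groups against both control groups gave 0 by limma as well, with a smallest adjusted p of 0.0606 and 2737 at an unadjusted p under 0.05.

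Whether the supplements turned the diet's differences back was tested with the AD animals split, so that the diet difference and the supplement difference shared no animal. Across 17999 probe sets, which are not independent replicates, the mean correlation over 4 splits was 0.130 (SD 0.155) for AD-GE, −0.0193 (SD 0.216) for AD-GE-RES and 0.0965 (SD 0.190) for AD-RES. Simulated arrays without any effect gave split values from −0.434 to 0.533, −0.404 to 0.553 and −0.434 to 0.589. Without splitting, the correlations were −0.225, −0.530 and −0.266, beside simulated medians of −0.488, −0.468 and −0.511, and the observed covariances differed from the simulated medians by 0.00698, −0.00430 and 0.00768. No opposition beyond that of the shared AD animals was detected.

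The probe sets called between males and females included sex-linked genes and some genes of immune cells. Others were STAMBPL1, DSE, RFX1, ZNF134, CBR3 and RPS13, and 29 had several symbols or none. No theme among them was tested. EIF1AY, a Y-linked translation factor, was higher in males by 6.35 (n = 12 for each sex, limma adjusted p = 1.27e-23). The female mean of 2.64 lay under the level of 3.57 used as the filter, so background signal may limit the size of this difference. No detection floor was determined. The X-linked genes USP9X, EIF1AX and KDM6A were lower in males, with differences of −0.51, −0.49 and −0.69, and the probe set annotated to ZFX was higher by 1.10. CXCR4 was higher in males by 0.64 (SE 0.12, limma adjusted p = 0.0187), as was SOCS1, which restrains cytokine signalling, by 0.64. CD40, the costimulatory receptor of B cells and monocytes, and the cannabinoid receptor CNR2 were lower, with differences of −0.52 and −0.53. The CXCR4 difference was not seen in CT, with females at 10.74 and 11.05 and males at 11.06 and 10.79. In AD the females stood at 11.10 and 11.24 and the males at 12.46 and 12.48. In all limma called 48 probe sets, 13 higher and 35 lower in males, of which 19 had 1 symbol, and 1857 had an unadjusted p under 0.05. EIF1AY, the stronger EIF1AX probe set and ZFX passed under every alternative run. CXCR4 (limma adjusted p from 0.000336 to 0.403), CNR2 (0.000477 to 0.691), USP9X (7.36e-06 to 0.0810) and KDM6A (0.00131 to 0.0810) passed in 32 of 33, all but the fit with list means of monocyte, B cell and erythroid genes, while SOCS1 (0.00511 to 0.356) passed in 11 and CD40 (0.00140 to 0.714) in 10 of 33. Without AD-GE-RES 1 242 probe sets were called.

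The difference between AD and CT also differed between the sexes, with 2 animals for each diet and sex. PSAT1, an enzyme of serine synthesis, differed by 0.34 between AD and CT in females and by −1.95 in males, a difference of −2.28 (SE 0.31, limma adjusted p = 0.0222). KMO, an enzyme of tryptophan breakdown, differed by −1.76 in females and 0.10 in males, a difference of 1.86 (SE 0.34, limma adjusted p = 0.0471). PSAT1 stood at 7.04 and 7.03 in the CT males and at 6.04 and 5.13 in the CT-GE-RES males, also on chow. KMO stood at 8.45 and 8.87 in the CT females, but also at 8.50 and 8.47 in the AD-RES males and 7.81 and 8.31 in the CT-GE-RES males. High KMO values were thus not tied to chow in 1 sex. For PSAT1 the highest values were those of males on chow, with the AD-RES males next at 5.73 and 5.57. MSMO1, a sterol synthesis enzyme, differed between the sexes by 1.78, the transcriptional repressor TGIF1 by 1.41 and the heat shock gene HSP70.2 by −2.08. Limma called 21 probe sets, 17 with the higher difference in males and 4 with the lower, and 2686 had an unadjusted p under 0.05. In all 21 the estimates had opposite signs in the sexes, which selection for an interaction favours. Some were small in 1 sex, such as KMO in males (0.10) and TGIF1 in females (−0.10), beside a median SE of 0.20. Between AD and CT limma called 242 probe sets in males and 1, KMO, in females. The count was 0 when only the AD and CT arrays were fitted, 0 with array weights, and, leaving out single arrays, 0 without CT 2, 0 without AD 4, 1 without AD 1, 1 without AD 3 and 961 without CT 3.

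**Figure D5:**
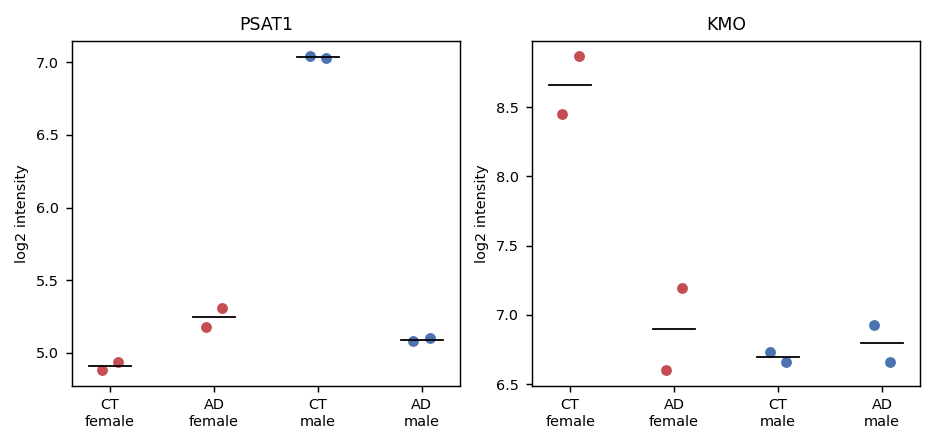
Log2 intensity (y axis) of PSAT1 and KMO in CT and AD animals by sex (x axis), with points for the 2 animals of each diet and sex, red female and blue male, and a line for their mean. From CT to AD the mean of PSAT1 differed by −1.95 in males, and that of KMO by −1.76 in females.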

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

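The test of the interaction of sex and diet with the 3'/5' ratio in the fit was chosen only after the result was seen.

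The difference between AD and CT differed between females and males for 21 probe sets by limma (2686 at an unadjusted p under 0.05), with PSAT1 and KMO among them. Of 100 draws of the diets within each sex 1, the real one, called as many, and the highest other gave 2. Chance assignment of all 6 diets within a sex can thus be excluded at that level. Each draw broke up the pairs of animals of every diet and sex, so the draws cannot exclude chance for AD against CT alone. The count was also not stable when single arrays were left out, which leaves 1 animal for a diet and sex. With the 3'/5' ratio in the fit 109 probe sets were called, all 21 among them, which argues against a linear effect of the ratio shared by all arrays. That fit cannot exclude an effect of array quality confined to single arrays, such as CT 4 (ratio 4.39, array weight 0.285). With array weights in the fit the count was 0. Each diet and sex had 2 animals, so anything else the 2 shared, such as litter, pen or day of sampling, cannot be told apart from sex and diet. A response to the diet that depends on sex stays open as a hypothesis; with only the AD and CT arrays in the fit the count was 0, and more animals for each diet and sex would test it.

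Single animals stood apart from the other 3 of their group in 9 of the 174 sets of 4 values tested (28 lists and the 3'/5' ratio in 6 groups), where chance flags about 1 in 20 groups (8.7 of them). Relative to the list's mean over all arrays, monocyte genes were at 0.69 in AD-GE-RES 1, neutrophil genes at 1.83 in CT 4 and erythroid genes at −0.37 in AD-GE 2. Cholesterol biosynthesis genes were at 0.22 in AD-GE-RES 2, fatty acid synthesis genes at 0.019 in AD-GE 1, inflammatory genes at 0.41 in AD-GE 4 and glucocorticoid response genes at 0.31 in CT-GE-RES 4. Circadian clock genes were at 0.30 in AD 4 and at 0.26 in AD-GE 4.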

How the results depend on the processing

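The 3'/5' ratio as a covariate, omission of CT 4 and AD-GE-RES 1 together, all 4 atherogenic groups against both control groups, and the interaction of sex with all 6 diets were tests chosen only after the data were seen. Where a result moved, the cause was not tested, except that a fit on fewer arrays has fewer degrees of freedom and that an unadjusted p is less strict than an adjusted one. With 4 animals in a group, limma called 34% of simulated 1.41-fold changes, so changes of that size may go uncalled, and transcripts under a mean log2 intensity of 3.57 were not tested. No paired analysis was possible because each animal was measured once. For the 171 named gene results, 3448 of 3732 values under alternatives kept their direction and side of the threshold, 257 no longer passed, 11 newly passed and 16 changed sign. For 50 list results the counts were 546 of 770 kept, 223 no longer passing and 1 with the opposite direction.

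Probe sets called by limma stayed at 0 in all 5 comparisons, in the difference between diets, among supplements and for the averaged diet in every fit with a single array left out. In females alone AD against CT gave 1 and AD-RES against AD 4; in males alone AD against CT gave 242, AD-RES against AD 7 and CT-GE-RES against CT 122. With the ratio in the fit the counts were 1 and 6 in females for AD against CT and AD-RES, 1 in females for CT-GE-RES, and in males 214 (91 higher and 123 lower, against 169 and 73), 22 and 6. Array weights gave 1 for AD-GE against AD, 56 among supplements, 806 between the sexes and 0 for sex by diet. Cell list means as covariates gave 1 among supplements, 21 between the sexes and 338 for sex by diet. An unadjusted p under 0.01 with a fold change of at least 1.5 gave 63, 74, 9, 42 and 30 for the 5 comparisons in order, 33 for the difference between diets, 65 for the averaged diet, 81 between the sexes and 850 for sex by diet. The 2 lowest-weight arrays left out gave 216 between the sexes and 147 for sex by diet. For sex by diet the count was 0 with its own arrays alone, 5 after repeated quantile normalization, 109 with the ratio and 46 over all 6 diets. With single arrays left out it ran from 0 to 961 (0 without CT 2 or AD 4, 1 without AD 1 or AD 3, 961 without CT 3), and between the sexes from 32 to 242 (242 without AD-GE-RES 1).

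Lists called were 0 with an estimated correlation and 0 with fry's directional test in each of the 5 comparisons, in the difference between diets and for the averaged diet; fry's mixed test called 1, the proteasome in CT-GE-RES. With the ratio in the fit 3 were called for AD against CT and 3 for the difference between diets, and 4 for the latter with the mean of all probe sets of a gene. With single arrays left out the counts ran from 6 to 12 for AD against CT (12 without CT 1), 2 to 9 for AD-GE (2 without AD 2, 3 without AD-GE 2, 8 without AD 1 or AD-GE 3, 9 without AD-GE 4), 4 to 10 for AD-GE-RES (4 without AD-GE-RES 2), 4 to 8 for AD-RES, 5 to 13 for CT-GE-RES (5 without CT-GE-RES 3), 3 to 7 for the difference between diets (3 without AD 2, 4 without AD 3, AD-GE-RES 1 or CT-GE-RES 3) and 6 to 10 for the averaged diet. List medians moved by over 1.5 times as follows. For AD against CT, without CT 1 they were −0.88 for platelet, 0.46 for glucocorticoid and −0.49 for cell cycle genes; without CT 3, −0.03 for platelet; without CT 4, 0.15 for T cell, 0.17 for glucocorticoid and −0.11 for cell cycle; without AD 1, 0.16 for immediate early; without AD 2, −0.95 for platelet and 0.14 for glucocorticoid; without AD 4, −0.27 for platelet and −0.16 for cell cycle. For AD-GE, apoptosis was −0.23 without AD 1, −0.24 without AD 4 and −0.096 without AD-GE 2, and NRF2 was −0.075 without AD 3. For AD-GE-RES, without AD-GE-RES 1 they were −0.56 for monocyte, −0.41 for inflammatory, −0.37 for glucocorticoid and −0.084 for apoptosis; without AD-GE-RES 2, 0.0033 for inflammatory, −0.065 for immediate early and −0.070 for glucocorticoid; without AD-GE-RES 3, −0.11 for monocyte and −0.31 for neutrophil; without AD-GE-RES 4, −0.26 for neutrophil; without AD 1, −0.16 for neutrophil and −0.18 for inflammatory; without AD 3, −0.86 for neutrophil, −0.14 for inflammatory and −0.069 for apoptosis. For AD-RES, erythroid was 0.24 without AD 3, monocyte −0.24 without AD-RES 1, and without AD-RES 2 inflammatory was −0.20 and adhesion −0.087. For CT-GE-RES, without CT 1 they were −0.15 for monocyte, 0.0036 for interferon and 0.12 for cell cycle; without CT 3, −0.46 for interferon; without CT 4, 0.20 for cytotoxic, −0.20 for neutrophil, −0.15 for erythroid and −0.14 for interferon; without CT-GE-RES 3, −0.12 for monocyte, −0.20 for interferon and −0.10 for immediate early; without CT-GE-RES 4, −0.39 for monocyte. The split correlations ran from 0.0673 to 0.184 for AD-GE, −0.136 to 0.137 for AD-GE-RES and −0.00780 to 0.145 for AD-RES.

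In females alone the difference changed sign for CAVIN2 (0.48), CENPF (0.48) and IL7R (−0.29) in AD against CT, for CXCL8 (0.56) in AD-GE-RES, for ABCA1 (−0.15) and RHCE (−0.80) in AD-RES, and for CD14 (−0.59), GZMH (−0.024) and KLF10 (0.24) in CT-GE-RES, as did CEBPD (0.031) in males alone. For AD-RES, ABCA1 ran from −0.040 (without AD 3, the only sign change) to 0.46 with single arrays left out, and CD14 stood at 0.69 with cell list means. For CT-GE-RES, where CD14 stood at 0.56, it ran from −0.080 (without CT-GE-RES 4) to 1.29 with single arrays left out, −0.0070 without CT 4, and was −0.51 with the ratio and −0.015 without the 2 lowest-weight arrays. The MHC class II list turned direction in the difference between diets with the ratio (camera adjusted p = 0.614).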

Other observations

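Chosen only after the results were seen were the tests of the diets for the 3'/5' ratio, and of the ratio and of monocytes in the supplemented groups for the glucocorticoid and immediate early genes. So were all tests of other splits or draws on counts of probe sets, except the draws for sex by diet. A condition on the spread of members in the test of the AD animals alone was also added then.

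With the diets pooled, interferon response genes were higher in males than in females in 22 of 26 with a median of 0.31 (camera adjusted p = 2.98e-08, and adjusted p = 0.966 with an estimated correlation). By limma 0 of its members passed over all genes and 0 adjusted over the list alone. The list mean in males minus females, with n = 2 for each sex, was −0.07 in CT, 0.33 in AD, 0.36 in AD-GE, 0.00 in AD-GE-RES, 1.08 in AD-RES and 0.32 in CT-GE-RES. Also higher in males by camera were ER stress genes, 12 of 15 with a median of 0.09 (0.0289), erythroid genes, 8 of 12 with 0.27 (0.0342), and glucocorticoid response genes, 11 of 14 with 0.18 (0.0425), each with an adjusted p = 0.966 with an estimated correlation. Of the glucocorticoid genes 1, CXCR4, passed over all genes and 1 adjusted over the list alone, and that list's call was lost with the 3'/5' ratio in the fit (camera adjusted p = 0.274). Without the 2 lowest-weight arrays 2 of these 4 calls remained, and those of the ER stress (0.112) and erythroid (0.489) lists were lost. Males were not higher in each diet: the difference was −0.41 in CT for glucocorticoid genes, −0.07 in AD and −0.08 in CT-GE-RES for ER stress genes, and −0.34 and −0.72 for erythroid genes. Whether these differences between diets exceed chance was not tested for lists. Monocyte genes stood in CT near AD, at 0.26 ± 0.24 (SD, n = 4) and 0.30 ± 0.12.

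The leading principal component followed the 3'/5' ratio over all arrays. The spiked transcripts, added to the samples in the laboratory, followed the same ratio with r 0.949, rho 0.837 and r 0.923 without the 2 farthest arrays (permutation p 1e-05, the smallest possible, adjusted 2e-05 over 2 relations), which is consistent with a difference arising in the labelling reaction. The ratio of a further pig control transcript, IRP, gave r 0.265, rho 0.204 and r 0.00911 without the 2 farthest with the leading component (permutation p 0.337), which decides nothing. Pig RNA shortened before the spiked transcripts were added would leave their ratio unchanged. Their r of 0.949 therefore argues against such shortening as the main source of the ratio's differences. Shortening of RNA after that point stays open. The ratio over the 6 diet groups had a permutation p of 0.498, which does not show that the diets were alike in it.

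Glucocorticoid response and immediate early genes were higher in AD than in CT and lower in AD-GE-RES and AD-RES than in AD, with a median of 0.262 for AD minus CT over both lists, calls lost with an estimated correlation (adjusted p = 0.764 for AD against CT, 0.596 for AD-GE-RES and 0.564 for AD-RES) and with medians for AD against CT of 0.02 and 0.08 in females and 0.60 and 0.32 in males. A lower share of monocytes may account for the part of the pattern seen with the supplements: over all 3 supplemented groups minus AD the median was −0.318, and −0.0310 with the monocyte mean in the fit. That mean was taken from expression and is not a cell count. Monocyte genes regulated together with the genes of both lists would give the same result, so the fit cannot show a change in share. For AD minus CT (0.249 with the monocyte mean) the test decides nothing, since that mean differed by 0.04 (SE 0.28). With the 3'/5' ratio in the fit the median for AD minus CT was 0.142, which leaves the ratio open as a partial cause. The AD animals enter all 4 comparisons: the mean of the 3 supplemented groups minus CT had a median of −0.0258 over these genes, but the members went both ways (quartiles −0.20 and 0.21), so AD animals that stood apart cannot be told apart from an effect of the diet that the supplements reversed. A response to the diet itself may remain as a hypothesis, which a second set of AD animals would test.

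Other splits of the same animals were counted for each result. In all 35 splits of 8 arrays as many probe sets were called as in the real one, which was 0 each time; the highest other gave 432, 1, 113, 0 and 3 for the 5 comparisons in order, and the 432 and 113 point to a structure of the samples, whose source was not tested; 2 and 4 of the 35 splits called any. For lists at the preset correlation 15, 16, 13, 14 and 14 of 35 splits gave as many as the real 7, 5, 7, 6 and 10, with highest others of 12, 13, 12, 13 and 13, so chance cannot be excluded for any of these counts. For the difference between diets, among supplements and the averaged diet, all 100 draws gave at least the real 0, with highest others of 444, 326 and 57. Between the sexes 4 of 100 draws, the real one included, gave as many called probe sets as the real 48. For probe sets at an unadjusted p under 0.05, 12 of 100 draws gave as many as the real 1857. The counts of this paragraph were not adjusted for their number, so chance cannot be firmly excluded for the count of 48. The highest other, 694, also points to a structure of the samples, whose source was not tested.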
